A study of Patiria miniata with 6 samples.

How the data were processed

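The series measured polyadenylated RNA of single cells from embryos of Patiria miniata, the bat star, a sea star. There were 6 samples, 1 for each of 6 developmental stages, which the labels give as 8, 10 and 14 hours post fertilisation (hpf), blastula, early gastrula and mid-gastrula. Per the labels, all embryos came from 1 pair of parents, fertilisations were timed so that every stage was reached together, and each stage used equal numbers of embryos. Cells were dissociated without centrifugation and encapsulated with the 10x Genomics Chromium droplet system, which labels each captured transcript with a cell barcode and a unique molecular identifier (UMI). The libraries used the 3′ version 3 chemistry, so each transcript was read near its polyadenylated end.

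For each sample, the authors deposited a matrix of UMI counts per gene and cell barcode, with no normalisation, together with the list of barcodes and the list of gene identifiers. The submitters' processing notes name Cell Ranger, with no version, and Seurat 3.1.4, and the deposited matrix headers record software version 3.1.0 without naming the program. The genome build, the annotation and the rule that selected barcodes as cells are not given in the sources used here. The matrices of the first 3 stages each held 1 barcode suffix, and those of the last 3 stages each held 2 suffixes, as Cell Ranger writes when it joins libraries. Whether reads were subsampled to equal depth before joining is not given in the sources used here. Each suffix was treated as a separate library when doublets and UMI distributions were examined. Suffixes were not treated as replicates, because the labels name 1 sample per stage.

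Every matrix held the same 30399 gene identifiers, all of the form PMI followed by a number, and the files do not pair them with gene names. The RefSeq gene table given for the species holds 27818 genes, and 0 of the 30399 identifiers matched it. For this reason the comparisons that needed gene names were not run. They were the level of germ cell factors, the share of cells with a nanos or a vasa UMI, the co-detection of nanos and vasa, the enrichment of nanos in its leading cluster, the medians of fixed gene lists and the assignment of cell types from markers. Genes are given by identifier alone, and nothing is said of their function.

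Barcodes with at least 500 UMIs and 200 detected genes were used. In each library, the barcodes with the highest Scrublet doublet scores were left out, up to 0.8% per 1000 barcodes. Scrublet was run through scanpy 1.11.5. UMIs of the kept barcodes were summed per stage and scaled to a stage total of 1000000 (UMI counts per 1000000, abbreviated CPM), and each level carries an exact 95% Poisson interval. A gene was called apart between a pair of stages by size alone. The summed levels had to be at least 4-fold apart, with at least 10 CPM in the higher stage and Poisson intervals that did not overlap. A stage with fewer than 3 UMIs of a gene was set to a floor of 3 UMIs for this rule. A fold against 0 UMIs is printed as a lower bound against that floor, and a ratio against 1 to 3 UMIs is printed without the floor, with an exact conditional binomial interval. With 1 sample per stage there was no test, p-value or standard error. Cells of 1 sample are not replicates, so all intervals cover counting error only. They leave out variation between embryos, dissociations, libraries and barcodes. The intervals also treat UMIs as independent, so they are too narrow for genes with most of their UMIs in a few barcodes. The rule that intervals must not overlap shares this limit.

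Genes named in stage comparisons were chosen by a rule. It took the 2 identifiers with the largest ratio in each direction among genes that passed the size rule and reached at least 50 CPM in the higher stage. For each cluster, the rule named up to 5 genes with the largest fold over the other cells of the stage among genes with a UMI in at least 25% of its cells, of which a few are printed. Genes named in the closing section for other patterns were chosen after their values were seen.

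Each stage was clustered alone. Counts were scaled to 10000 UMIs per barcode and log transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was divided with the Leiden method at a resolution of 1 with a fixed seed (igraph 0.11.9). Clusters of consecutive stages were matched by the Pearson correlation, across genes, of their log ratios to the other cells of the stage. Genes had to reach 20 CPM in a cluster, or in the cells outside it, at both stages. A match was called reciprocal when each cluster was the other's best match. Correlations between profiles are across genes within samples, and genes are not independent replicates. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

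The distribution of UMIs per barcode had a low and a high mode in 8 of the 9 libraries, separated by a valley. An analysis restricted to barcodes above the valley was added after the data were seen. The second blastula suffix, which had no valley, entered it whole, with 4338 of the 7589 blastula barcodes used there. Other settings added after seeing the data were keeping called doublets, leaving out each gene's 5 highest barcodes in every stage, and all alternatives for the clusters. The alternatives fixed before the data were examined were a minimum of 50 CPM or none, a 2-fold limit, trimmed mean scaling between stages, a minimum of 1000 UMIs per barcode, and leaving out each suffix in turn. Their effects are given in the closing section.

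The size rule was tested on simulated data at the depths of these stages. Of 100 genes changed 8-fold at each step it called 97 to 100, of 100 genes changed 2-fold it called 0, and it called 0 unchanged genes. The simulated counts varied by Poisson sampling alone, without the spread between barcodes and libraries seen in the data. The 0 calls are therefore no estimate of false calls in the data. The kept barcodes held from 3003980 UMIs at 8 hpf to 59006844 at mid-gastrula. The floor of 3 UMIs therefore stood at 0.999 CPM at 8 hpf, 0.180 CPM at 10 hpf, 0.175 CPM at 14 hpf, 0.0991 CPM at blastula, 0.135 CPM at early gastrula and 0.0508 CPM at mid-gastrula. Levels at 8 hpf were the least precise.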

Results

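Single-cell RNA profiles were collected from bat star embryos at 6 stages, with 1 sample per stage. The series concerns how factors of the germ line are regulated in an embryo whose germ cells arise by induction, that is, through signals from other cells. The deposited matrices held 1000 barcodes at 8 hpf, 3129 at 10 hpf, 3278 at 14 hpf, 9500 at blastula, 10117 at early gastrula and 21174 at mid-gastrula. Their totals were 3024741, 17430233, 17906686, 31907503, 23493191 and 63778225 UMIs in the same order. After filtering, 992, 3051, 3192, 9138, 8823 and 19361 barcodes remained. The minimum of 500 UMIs removed 923 barcodes, all of them at early gastrula. The median kept barcode held 2435 UMIs at 8 hpf, 2312 at 10 hpf, 4817 at 14 hpf, 2836 at blastula, 1120 at early gastrula and 1733 at mid-gastrula. Between 20223 and 26766 of the 30399 genes had a UMI in a stage. Because each stage was a single sample, no difference below was tested against replicate spread, and the 95% intervals describe counting error alone.

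UMIs per barcode fell into a low and a high mode in all libraries except the second suffix of the blastula. The number of kept barcodes above the valley was 115 of 992 at 8 hpf, 1237 of 3051 at 10 hpf, 2711 of 3192 at 14 hpf, 4173 of 8823 at early gastrula and 9038 of 19361 at mid-gastrula. In the first suffix of the blastula, 3251 of 4800 kept barcodes lay above it. The median barcode below the valley held 2372 UMIs at 8 hpf and 1190 at 14 hpf, against 7517 and 5259 above it.

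**Figure D1:**
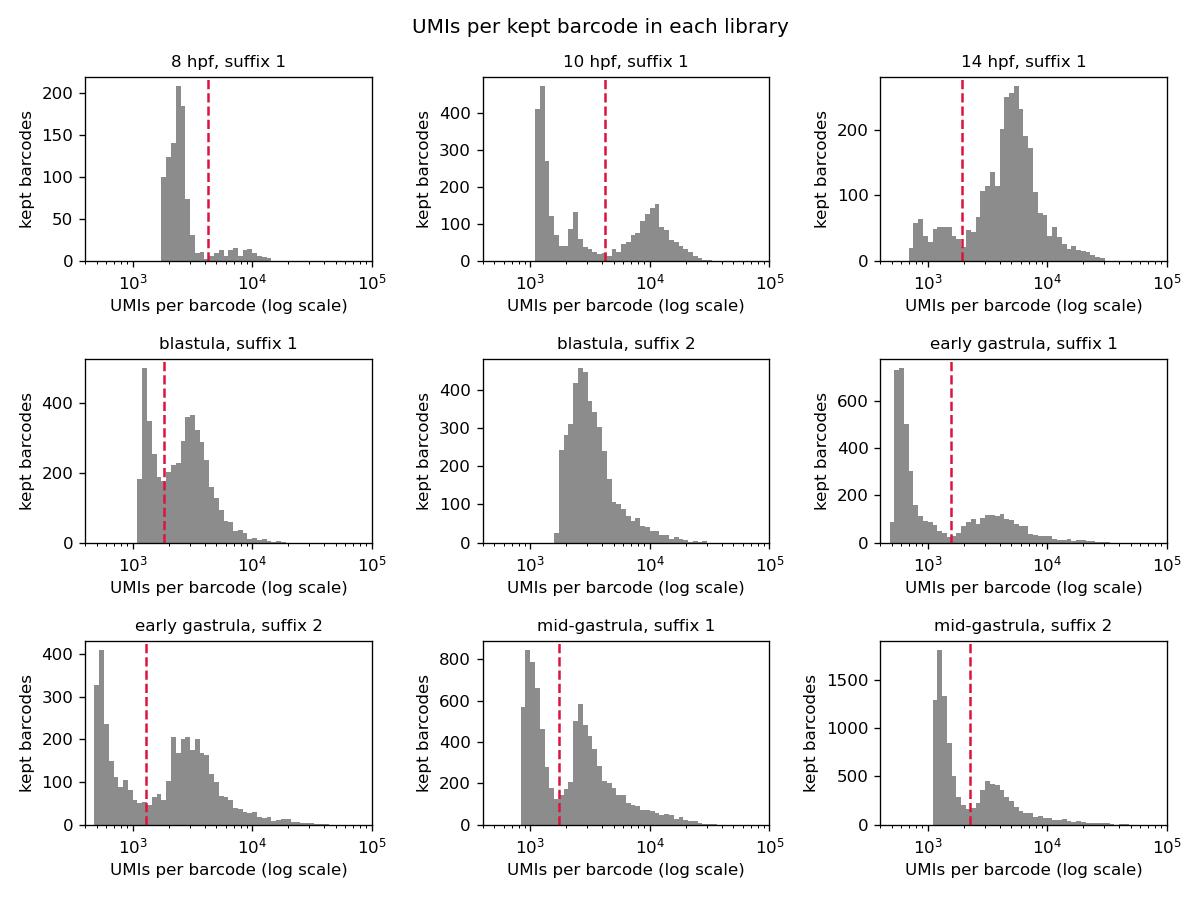
Number of kept barcodes (vertical axis) against UMIs per barcode (horizontal axis, log scale) in each of the 9 libraries, with the valley between the low and the high mode as a dashed line. The 8 hpf library has 115 of 992 barcodes above its valley, the 14 hpf library has 2711 of 3192, and the second blastula library has no valley.

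The gene PMI_019456 had the highest level at the first 3 stages, at 44408, 66468 and 35156 CPM, and stood at 6090 CPM at mid-gastrula. PMI_007245 had the highest level at the last 3 stages, at 22110, 24012.5 and 23751 CPM. The profiles of 11562 genes with at least 10 CPM in some stage were closest between early gastrula and mid-gastrula (Pearson r = 0.977 across genes) and between blastula and early gastrula (r = 0.976). They were further apart between 14 hpf and blastula (r = 0.793) than between 8 and 10 hpf (r = 0.954) or 10 and 14 hpf (r = 0.928). The first and the last stage had an r of 0.587. The labels give no hours for blastula and the later stages, so the lengths of the last 3 steps are not known here. The suffixes of a single stage gave r = 0.993 at blastula, 0.989 at early gastrula and 0.996 at mid-gastrula, with 8, 17 and 5 genes apart between suffixes by the size rule.

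**Figure D2:**
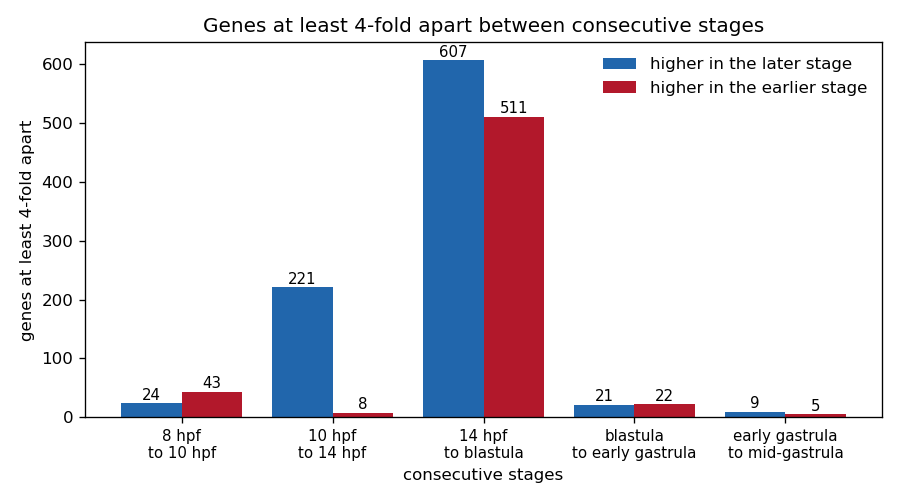
Number of genes (vertical axis) at least 4-fold apart between each pair of consecutive stages (horizontal axis), with genes higher in the later stage in blue and genes higher in the earlier stage in red. The step from 14 hpf to blastula has 607 and 511 genes, against 24 and 43 genes from 8 to 10 hpf and 9 and 5 genes from early gastrula to mid-gastrula.

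From 8 to 10 hpf, few genes differed by the size rule. PMI_029211 stood at 0.666 CPM at 8 hpf (2 UMIs, 95% interval 0.0806 to 2.41) and at 71.2 CPM at 10 hpf (67.2 to 75.3), a ratio of 107 with a counting interval of 29.5 to 884. PMI_019185 was 63.8-fold higher at 10 hpf, at 212 CPM against 3.33 CPM (1.60 to 6.12). PMI_003834 was 81.8-fold lower at 10 hpf, at 1.38 CPM (0.874 to 2.07) against 113 CPM (101 to 126). PMI_028353 was 73.4-fold lower, at 1.08 CPM (0.640 to 1.71) against 79.2 CPM (69.5 to 89.96). In all, 24 genes were higher at 10 hpf and 43 were higher at 8 hpf, of 9842 genes at 10 CPM or more. At 8 hpf a single barcode held 216 of the 339 UMIs of PMI_003834, and a single barcode held 146 of the 238 UMIs of PMI_028353. Without the 5 highest barcodes of each gene, 17 UMIs of each remained at 8 hpf and neither gene passed the 10 CPM minimum, though this removal takes a larger share of the UMIs at 8 hpf than at 10 hpf, as with PMI_019185, which kept 3 of 10 and 3355 of 3543. The split turned with at least 50 CPM (14 higher and 7 lower at 10 hpf) and a 2-fold limit (278 and 266). It also turned without each gene's 5 highest barcodes (49 and 14), subject to the same unequal removal. Above the UMI valley the log2 values were bounds of 4.54 for PMI_029211 and -10.12 for PMI_003834, and ratios of 5.37 for PMI_019185 and -9.10 for PMI_028353. The values of PMI_003834 and PMI_028353 there rest mainly on 1 barcode each. At 8 hpf the genes had 221 and 146 UMIs above the valley, of which the highest barcode held 216 and 146.

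From 10 to 14 hpf, the genes that differed were mostly higher at 14 hpf. PMI_001250 stood at 2.16 CPM (1.51 to 2.99) at 10 hpf and 302 CPM (294 to 311) at 14 hpf, which was 140.0-fold higher. PMI_021998 stood at 3.24 CPM (2.43 to 4.22) and then 324 CPM (316 to 333), which was 100.1-fold higher. PMI_019185, already higher at 10 than at 8 hpf, reached 3533 CPM at 14 hpf, and PMI_029211 reached 351 CPM. Of 9916 genes, 221 were higher at 14 hpf and 8 were lower, and none of the 8 reached 50 CPM at 10 hpf. With no CPM minimum, 626 genes were higher and 197 lower. Trimmed mean scaling shifted the log2 ratio of every gene by 0.20 and gave 268 genes higher and 2 lower. With a 2-fold limit the split turned, with 483 genes higher and 559 lower at 14 hpf.

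From 14 hpf to blastula, the profile differed most among consecutive stages, and genes differed in both directions. PMI_006940 was at 0.234 CPM at 14 hpf (4 UMIs, 0.0637 to 0.599) and at 592 CPM at blastula (584 to 601), which was 2533-fold higher. PMI_015499 had 1 UMI at 14 hpf and stood at 273 CPM at blastula (267 to 279), a ratio of 4664 with a counting interval of 837 to 184226. PMI_012408 was at 52.2 CPM at 14 hpf (48.8 to 55.7) and had 0 UMIs at blastula, so that it was at least 526-fold lower, a log2 bound of -9.04 that became -8.16 and -7.91 with a single blastula suffix. It had 1 UMI at 8 hpf and was at 2.94 CPM at 10 hpf, so 14 hpf was its highest stage. PMI_003606 was 15.7-fold lower at blastula, at 3.60 CPM (2.96 to 4.34) against 56.4 CPM (52.9 to 60.05), after 92.2 CPM at 8 hpf and 101 CPM at 10 hpf. Of 10249 genes, 607 were higher and 511 were lower at blastula, 10.9% together. A single blastula barcode held 2326 of the 17931 UMIs of PMI_006940, and without their 5 highest barcodes it was at least 1567-fold and PMI_015499 at least 717-fold higher, each against 0 UMIs at 14 hpf. This removal leaves most barcodes rich in PMI_015499 in place. Outside a blastula cluster of 16 barcodes, described below, only 894 of the 8254 UMIs of PMI_015499 remained. With a 2-fold limit 2002 genes were higher and 2207 were lower, so the split turned.

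From blastula to early gastrula, 21 genes were higher and 22 were lower of 9643, which became 188 and 53 with a 2-fold limit and 253 and 62 with no CPM minimum. PMI_000681 was 14.6-fold higher at early gastrula, at 101 CPM (96.4 to 105) against 6.87 CPM (5.97 to 7.87), and it stood at 219 CPM at mid-gastrula. PMI_002061 was 8.66-fold higher, at 62.4 CPM (59.1 to 65.8) against 7.20 CPM (6.28 to 8.23). PMI_006472 was 113-fold lower, at 0.766 CPM (0.446 to 1.23) against 87.0 CPM (83.7 to 90.4), and stood at 40.6 CPM at mid-gastrula. PMI_022715 was 86.0-fold lower, at 0.676 CPM (0.378 to 1.12) against 58.2 CPM (55.5 to 60.9), and stood at 25.7 CPM at mid-gastrula. A single blastula barcode held 1672 of the 2632 UMIs of PMI_006472, and a single barcode held 1004 of the 1760 UMIs of PMI_022715. Neither gene passed the size rule without its 5 highest barcodes (14.1- and 10.5-fold) or without the second blastula suffix (log2 ratios of -2.57 and -2.02, against -7.67 and -7.28 without the first), and without the 5 highest barcodes 21 genes were higher and 11 were lower, while leaving out any 1 suffix gave 20 to 26 higher and 13 to 32 lower.

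From early gastrula to mid-gastrula the fewest genes differed, with 9 higher and 5 lower of 9836, no more than the 17 genes apart between the suffixes of early gastrula alone. PMI_028073 was 8.59-fold higher at mid-gastrula, at 56.9 CPM (55.0 to 58.9) against 6.63 CPM (5.60 to 7.79), and was the 1 higher gene that reached 50 CPM. PMI_005228 was 5.22-fold lower, at 22.0 CPM (20.8 to 23.3) against 115 CPM (111 to 119). PMI_006890 was 4.48-fold lower, at 17.1 CPM (16.03 to 18.2) against 76.5 CPM (72.9 to 80.2). Without the second suffix of the early gastrula, PMI_006890 no longer passed the rule (log2 ratio of -1.66), and 9 genes were higher and 14 lower. The split also turned without the second suffix of the mid-gastrula, with 3 genes higher and 10 lower, with a 2-fold limit, with 67 higher and 121 lower, and with no minimum, with 60 higher and 139 lower.

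Over the whole series, 1406 of 10894 genes were higher at mid-gastrula than at 8 hpf and 1232 were lower, 24.2% together. PMI_001310 was 6325-fold higher, at 12632.5 CPM (12604 to 12661) against 2.00 CPM (6 UMIs, 0.733 to 4.35). It stood at 9.71 CPM at 10 hpf, 906 CPM at 14 hpf, 12672 CPM at blastula and 15903 CPM at early gastrula. PMI_017806 had 0 UMIs at 8 hpf and stood at 677 CPM at mid-gastrula (671 to 684), at least 678-fold higher. PMI_008208 was 46.8-fold lower, at 3.34 CPM (2.89 to 3.84) against 156 CPM (142 to 171). PMI_028353 was 39.0-fold lower, at 2.03 CPM (1.69 to 2.43). Without the 5 highest barcodes PMI_008208 was 12.4-fold lower, and PMI_028353 was 11.1-fold lower and no longer passed the rule. The log2 ratio of PMI_028353, -5.28, became -4.80 without the first mid-gastrula suffix and -6.20 without the second. Above the UMI valley it was -6.31, where 1 barcode held all 146 UMIs of the gene at 8 hpf. Above the valley the log2 ratio of PMI_008208 was -4.61 and the bound of PMI_017806 was 7.68. Trimmed mean scaling shifted every log2 ratio by 0.32, and with it 1926 genes were higher and 796 lower, but the split turned with at least 50 CPM (666 and 708) and with a 2-fold limit (2942 and 3220).

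**Figure D3:**
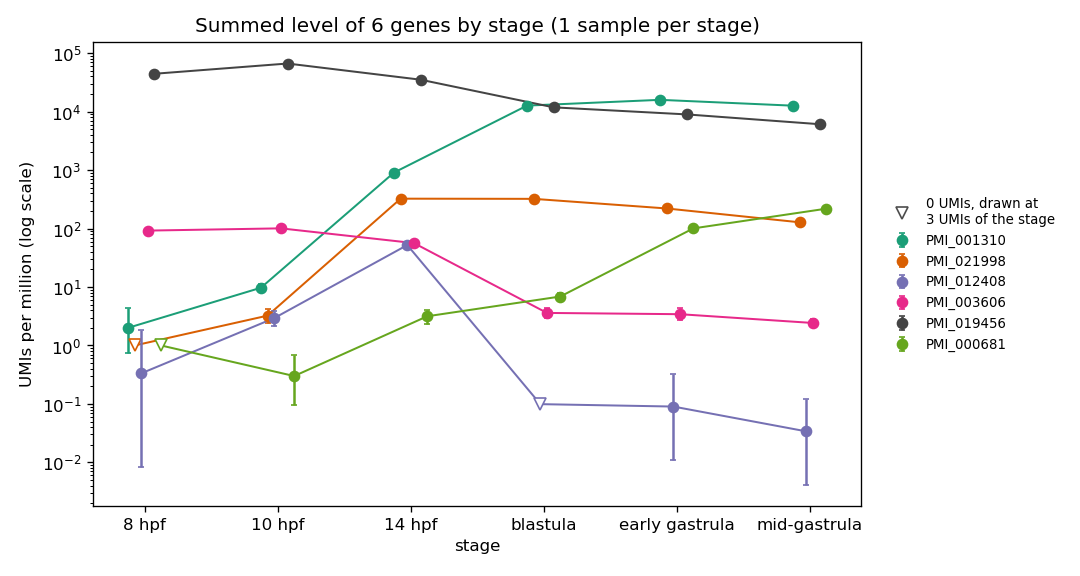
Summed level of 6 genes in CPM (vertical axis, log scale) at each stage (horizontal axis), with exact 95% Poisson intervals as bars and open triangles at the floor of 3 UMIs where a gene had 0 UMIs. PMI_001310 passes from 2.00 CPM at 8 hpf to 12672 CPM at blastula, PMI_012408 stands at 52.2 CPM at 14 hpf and has 0 UMIs at blastula, and PMI_000681 stands at 219 CPM at mid-gastrula.

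Clustering each stage alone asked how transcript levels were distributed among cells, since germ line factors are studied here as a matter of cell fate. It gave 12 clusters at 8 hpf, 6 at 10 hpf, 8 at 14 hpf, 13 at blastula, 11 at early gastrula and 8 at mid-gastrula. Many early clusters were hardly set apart by genes at least 4-fold higher than in other cells, at 50 CPM or more. The median number of such genes per cluster was 0.5 at 8 hpf, 0.5 at 10 hpf and 1 at 14 hpf. It was 5 at blastula, 21 at early gastrula and 8.5 at mid-gastrula. The cluster numbers are therefore not numbers of cell populations. At 14 hpf, a cluster of 358 of 3192 barcodes had PMI_029211 at 1907 CPM, 14.5-fold over the other cells of the stage. PMI_021998 led another cluster of 609 barcodes, at 788 CPM and 4.35-fold over other cells. At blastula, PMI_021998 led a cluster of 898 of 9138 barcodes, at 1822 CPM and 13.3-fold over other cells. At mid-gastrula the gene was 13.8-fold higher in a cluster of 1147 of 19361 barcodes, at 848 CPM. The 14 hpf cluster led by PMI_021998 was closest to a different blastula cluster (r = 0.37). The blastula cluster was closest to an early gastrula cluster led by another gene (r = 0.68), and neither match was reciprocal. Above the UMI valley, the blastula and early gastrula clusters led by PMI_021998 matched reciprocally (r = 0.76), as did the latter and a mid-gastrula cluster (r = 0.79). A blastula cluster of 1149 barcodes had 164 genes at least 4-fold higher and 92 lower than in the other cells. Its leading gene, PMI_011119, stood at 133 CPM, 43.9-fold over other cells. The best match of this cluster at early gastrula was a cluster of 880 of 8823 barcodes (r = 0.93 across 8619 genes), where PMI_011119 was 50.5-fold higher. That cluster in turn was best matched by a mid-gastrula cluster of 2160 barcodes (r = 0.94 across 7832 genes), led by PMI_028819 at 12.3-fold. Both matches were reciprocal. Above the UMI valley, PMI_011119 led a cluster of 596 barcodes at blastula (53.2-fold) and 1 of 414 at early gastrula (102-fold), beside clusters of 433 and 329 barcodes where PMI_025354 was 19.2- and 15.1-fold higher, which matched each other reciprocally.

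Some of the genes that differed between stages were found mainly in a small cluster. PMI_002061, higher at early gastrula than at blastula, stood at 1703 CPM in an early gastrula cluster of 166 barcodes and at 16.3 CPM in the remaining cells. PMI_015499, higher at blastula than at 14 hpf, stood at 128962 CPM in a blastula cluster of 16 barcodes and at 29.6 CPM in the remaining cells. Cluster numbers varied with the resolution, and 11 of the 12 clusters at 8 hpf, 3 of 6 at 10 hpf, 1 of 8 at 14 hpf, 2 of 13 at blastula, 3 of 11 at early gastrula and 4 of 8 at mid-gastrula consisted mostly of barcodes below the UMI valley. Above the valley, clustering gave 4, 7, 6, 12, 11 and 12 clusters in stage order.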

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

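Among the 60 counts of genes apart between stages obtained under alternative settings, 42 stayed within 1.5 times the count reported and 18 did not, mainly because the rule itself was altered. With at least 50 CPM in the higher stage, the 5 consecutive steps gave 21, 95, 516, 14 and 3 genes, and mid-gastrula against 8 hpf gave 1374. With no minimum the consecutive steps gave 248, 823, 2437, 315 and 199 genes, and with a 2-fold limit 544, 1042, 4209, 241 and 188, with 6162 for mid-gastrula against 8 hpf. Under each of these settings the step from 14 hpf to blastula had the most genes of the 5 consecutive steps. Leaving out the second early gastrula suffix gave 23 genes between early gastrula and mid-gastrula, and the cause was not tested. Of 149 ratios of named genes under alternatives, 129 stayed between the ratios of the outer Poisson limits, taken with counts raised to 3 UMIs where lower, 20 did not, and 0 changed sign, while 141 still passed the size rule. The 8 that failed it were those of PMI_003834 (log2 -4.98 against the floor), PMI_028353 (-3.98 against 10 hpf and -3.48 against mid-gastrula), PMI_006472 (-3.82) and PMI_022715 (-3.39) without their 5 highest barcodes, all below 10 CPM, and those of PMI_006472, PMI_022715 and PMI_006890 without 1 suffix, given with each comparison.

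All alternatives for the clusters were chosen after seeing the data. Of 42 cluster numbers, 31 stayed within 1.5 times the number reported. Leiden resolution 2.0 gave 33, 22, 17, 21, 31 and 27 clusters in stage order, and resolution 0.5 gave 3 at 8 hpf, 4 at 14 hpf, 5 at early gastrula and 5 at mid-gastrula. Barcodes above the UMI valley gave 4 clusters at 8 hpf, where 115 barcodes remained. Depth limits low levels at 8 hpf most, since the floor of 3 UMIs stood at 0.999 CPM there, against 0.0508 CPM at mid-gastrula. The comparisons that need gene names, with all their alternatives, were not run, because the identifiers could not be paired with names. They were the level of germ cell factors, the shares of cells with nanos or vasa UMIs, their co-detection, the enrichment of nanos in its leading cluster and the medians of gene lists.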

Other observations

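The second matching in the test of the step from 14 hpf to blastula and the test of amplification in single barcodes were chosen after their results could be seen, as were all gene and cluster patterns described in this part, while the other 3 tests were fixed before. Of 5575 genes with at least 50 CPM in some stage, 1480 had their highest level at 8 hpf, 933 at 10 hpf, 646 at 14 hpf, 698 at blastula, 496 at early gastrula and 1322 at mid-gastrula. A level that declined at every step and by at least 4-fold in all was seen in 109 genes, such as PMI_014342, with 5275 CPM at 8 hpf, 3109 CPM at 14 hpf, 927 CPM at blastula and 435 CPM at mid-gastrula. A level that increased at every step and by at least 4-fold in all was seen in 143 genes. Another 15 genes peaked in between, at least 4-fold above both ends, among them PMI_010407, with 574 CPM at 8 hpf, 4462 CPM at 14 hpf and 319 CPM at mid-gastrula. With barcodes above the UMI valley alone, 152 genes declined and 233 increased at every step, of which 43 and 72 were shared with the lists from all kept barcodes, so membership depended on that choice.

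Part of the genes whose mid-gastrula UMIs lay mainly in 1 cluster had 10 CPM or more at 8 hpf. Above the UMI valley, 90 of 6680 mid-gastrula genes with at least 20 CPM, and with at most 10% of their UMIs in any 1 barcode, had at least 50% of their UMIs in 1 cluster holding at most 20% of the stage's UMIs, and 81 of the 90 shared a single cluster of 1414 barcodes. Of the 90 genes, 41 had at least 10 CPM at 8 hpf (45.6%), against 88.9% of other genes with like numbers of mid-gastrula UMIs. For these 41 genes, the level in the highest cluster over the stage level had a median of 1.33 at 8 hpf, 1.44 at 10 hpf, 1.51 at 14 hpf, 5.88 at blastula, 5.32 at early gastrula and 4.46 at mid-gastrula. The 8 hpf median covers 26 of the 41 genes, those with at least 20 UMIs there. PMI_015267, for example, stood at 134 CPM at 8 hpf and 1074 CPM at mid-gastrula, while PMI_003448 had 0 UMIs at 8 hpf and stood at 567 CPM at mid-gastrula. The 41 genes were chosen by their concentration at mid-gastrula, so the high mid-gastrula ratio follows from that choice. The clusters were also drawn from the same counts, which favours concentration. Above the valley, 8 hpf had 4 clusters, each with over 20% of the stage's UMIs, against 12 at mid-gastrula. The 8 hpf ratio was therefore bounded by cluster size. The bound differed among later stages too. The cluster with most concentrated genes held 7.92% of UMIs at blastula, 9.71% at early gastrula and 13.2% at mid-gastrula. The medians are therefore not directly comparable between stages. With all kept barcodes 74 genes were concentrated and 31.1% of them had at least 10 CPM at 8 hpf, and with at least 66% of UMIs in 1 cluster the values were 33 genes and 30.3%.

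At 8 hpf, 1 cluster of all kept barcodes, with 54 of 992, had 334 genes at least 4-fold higher than in the remaining cells, against at most 39 in each of the other 11 clusters. In 38 of the 54 barcodes, these genes held over 5% of the UMIs, so part of the cluster carried the difference. Of the 94 clusters of later stages, with and without the valley, its profile was closest to a blastula cluster of 24 barcodes (r = 0.44 across 8271 genes), and that cluster was in turn closest to it among 85 clusters of other stages. The next closest was a 10 hpf cluster (r = 0.37). The blastula cluster had PMI_015499 at 56271 CPM, a gene that marks the rare barcodes dominated by PMI_006940 described last. Both genes had 0 UMIs at 8 hpf, so the match does not rest on shared UMIs of these genes. The blastula cluster of 16 barcodes with the highest level of PMI_015499 was also less close (r = 0.24). The origin of the match is open. The genes PMI_024749 and PMI_024879, with a trough between 8 hpf and mid-gastrula, had 63 of 72 and 85 of 92 of their 8 hpf UMIs in the 8 hpf cluster of 54 barcodes.

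The barcodes below the UMI valley may be free RNA captured without a cell, or cells with little RNA. Free RNA would vary among barcodes only by sampling. In a simulation from blastula alone, the excess dispersion of variable genes in such barcodes was -17.2% of that in cells. It was 115% for shallow cells. These shallow cells were blastula barcodes above the valley thinned to 500 UMIs, as were the cells they were compared with. The 115% therefore does not show what cells with little RNA would give. At an equal 500 UMIs, the excess dispersion below the valley was a median of 59.8% of that above it over 7 libraries, with a range of 40.8 to 139%. In no library did it drop to the 25% below which free RNA alone was expected, but 2 of the 7 lay under the 50% set against it, and the 8 hpf library, which has the largest share of such barcodes, showed no positive excess on either side. By library, the values were 124% at 10 hpf, 139% at 14 hpf and 106% in the first blastula suffix, above that 50%. They were 40.8 to 59.8% in the gastrula libraries. The 10 hpf value rests on a small excess, 0.0253 above the valley and 0.0313 below it. Over the libraries together, free RNA and shallow cells therefore cannot be told apart, and no biological explanation was tested.

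The step from 14 hpf to blastula was the largest, and it is also the step between matrices with 1 barcode suffix and matrices with 2, so a technical difference between these sets of files might contribute. If genes higher at blastula had already begun to increase between 10 and 14 hpf, within files of the same kind, that would argue against it. In the test fixed first, 36.6% of 546 such genes were at least 2-fold higher at 14 than at 10 hpf, against 36.2% of other genes of like mean level at 10 and 14 hpf, a ratio of 1.01. The second matching used the 10 hpf level alone and also dropped the CPM minimum, so 2 things changed, and the shares were 38.2% of 607 genes and 5.11%, a ratio of 7.48. The first matching cannot weigh the explanation, because its other genes were chosen partly by their 14 hpf level, which is also part of the change measured. Under the second, 4.12% of the genes lower at blastula were already at least 2-fold lower at 14 hpf, against 4.27% of other genes, a ratio of 0.963. The ratio for lower genes was 2.1 under the first matching, and their median dropped from 62.2 CPM at 10 hpf to 47.7 CPM at 14 hpf, against 62.3 to 57.7 CPM in the others of the second. These values do not settle it. Without the first blastula suffix 1213 genes were apart at this step, and without the second 1071, against 1118 with both. The count therefore did not depend on summing 2 suffixes, though each suffix still came from a joined matrix. Other differences between the sets of files cannot be told apart from the stage, and the change of stage itself stays open as untested.

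A few barcodes were dominated by PMI_006940. It made up at least 5% of the UMIs of 30 barcodes, 16 at blastula, 2 at early gastrula and 12 at mid-gastrula, in both suffixes of each stage and up to 38.6% of a barcode's UMIs, and in 0 barcodes of the first 3 stages, which allows up to 0.302%, 0.0983% and 0.0940% of their barcodes. An amplification or counting artefact in single barcodes would not recur with a second gene. Of the 30 barcodes, 29 had over 1% of their UMIs in PMI_015499, against 13 of 37292 other barcodes, a ratio of 2773. PMI_015499 was chosen after it had been seen in these barcodes, so the ratio cannot weigh this explanation. It shows only that the 2 genes recurred together. Cells or RNA from another organism might be a source. Outside the recurring genes, the share of these barcodes' UMIs on the 200 most abundant genes of their stage was a median of 83.3% of that in other barcodes, with an interquartile range of 68.2 to 97.5% that spans the 80% set as the bound, so this source stays open, and no biological explanation was tested.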
